A study of Mus musculus with 24 samples.

How the data were processed

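Total RNA of brain, heart and kidney from 8 mice was measured on Illumina mouse bead arrays, 24 arrays in all, after extraction with Trizol and column clean-up and labelling of amplified RNA with biotin, per the labels' protocols. The authors deposited an average bead intensity and a detection p-value for each of 25697 probes on each array, not normalized, per the file headers; GenomeStudio 2011.1 is named in the submitters' processing notes. The detection p-value in the deposited table compares a probe with the negative controls of its array, per the file headers and the values. A further deposited table by the authors gives a processed intensity on a linear scale. In that table the order of the probes on each array equalled that of the unnormalized signals (Spearman correlation 1), the quartiles were close within an organ, and 23.2%, 24.6% and 26.0% of values were below 0 in brain, heart and kidney. The median was 6.34 to 6.37 in brain, 5.10 to 5.12 in heart and 3.20 to 3.21 in kidney. The method of that normalization is not given in the sources used here.

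Groups came from the sample titles (organ, genotype and replicate number), and mice from the mouse numbers in the labels. The groups are 4 wild-type and 4 heterozygous mice per organ, and the mice are separate animals. The sample number, a running number in the sample descriptions, was used as an order within each organ. It has no stated meaning. No 2 arrays held identical values. Probes were named through the platform annotation, where 23978 had 1 gene symbol, 0 had several and 1719 had none. Symbols were checked through gene identifiers against the RefSeq gene table of GRCm38.p6, and 0 needed an update. The mutated gene Kctd1 has no probe under its name in that annotation, and its level is not analysed here, so that the labels were not checked by it. No coordinates were used.

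Each organ was normalized alone with neqc of limma 3.58.1 in R 4.3.3, which corrects the background with the detection p-values, adds an offset of 16 and quantile-normalizes the log2 values. Probes with a detection p under 0.05 on at least 4 of the 8 arrays of the organ were tested with lmFit and eBayes, heterozygote minus wild type, with Benjamini-Hochberg adjustment over all probes of the organ. Errors of log2 changes are the moderated standard errors of limma. Differences between organs were tested on within-mouse differences of values normalized over all 24 arrays, for probes detected on at least 4 arrays of either organ, and the average over organs on the mean of 3 organs per mouse, for probes detected on at least 4 arrays of each organ. Where no array of a group detected a probe, a fold is given as a lower bound, against the dimmest detected signal on each array of that group or the probe's own signal if higher.

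Gene lists were tested with camera, with a preset correlation of 0.01 and with an estimated correlation, on the brightest probe of each gene, for lists of at least 5 measured genes. The 55 lists hold 958 genes, 833 of them on the array, and cover cell types, segments and pathways of each organ and markers of cells that a dissection can bring along. For members of a list, p-values were also adjusted over the list alone. For lists that passed and for the distal convoluted tubule, the mean over the list was compared by an exact two-sided permutation test over the 70 assignments of 8 mice, which cannot give a p below 0.0286. Lists that passed were picked on the same arrays, and these p-values were not adjusted over lists, so they are no independent support. Correlations of the first principal component of the tested probes with the sample number were tested by exact permutation.

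The tests, samples, lists and alternatives, and the rule for naming genes, were fixed before the data were examined. The rule names the probes past the test, up to 15 with the largest rise and 15 with the largest fall, then, where fewer than 20 passed, those of smallest p up to 20 whose 4 heterozygous values all lie on one side of the 4 wild-type values. It also names members of a list past the test over the list alone, the 4 members of smallest p of each list that passed, and the 10 probes of smallest p for differences between organs and for the average. Probes without a symbol, or with a clone or locus number, were counted and passed over. Rab15, Cyb5a, Umod, Havcr1, Tfap2b, Nppa and Nppb were named outside this rule, after their values were seen, as were the lists named without having passed.

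Alternatives were no background correction, normalization over all 24 arrays, the authors' normalized values with a floor of 16, no detection filter, a filter of detection p under 0.01 on all 8 arrays, a trended robust prior, array weights, all 24 arrays in 1 fit with the mouse as a random block (statmod 1.5.0), the replicate number as a block, an adjusted p under 0.10, and leaving out each mouse. A term for the sample number was added after the data were seen. The tests were tested on simulated data with the spread of the real probes: with 100 probes changed by 1 and 100 by 0.5 on the log2 scale, 92 and 42 were found in kidney with 6 false calls, and 0 probes were called where nothing was changed. For the differences of kidney from brain, 83 and 20 of 100 were found, and from heart 73 and 11. Both sets were changed in the same simulation, which eases the adjusted threshold, so these shares do not hold for a few isolated changes. The simulated probes varied independently of each other and held no change along the sample number. The real arrays did hold such a change, so the simulated false calls do not give those of the real data.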

Results

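Transcripts were measured in brain, heart and kidney of 8 mice with Illumina mouse bead arrays, 1 array per organ and mouse. Per the labels, 4 mice were heterozygous for a mutation of Kctd1, a gene of the potassium channel tetramerisation domain family, and 4 were wild type. All were of the strain C3HeB/FeJ and 18.5 weeks old. The design text of the series speaks of 5 wild-type mice, while the labels name 4. Mouse numbers in the labels show that the same 8 mice gave all 3 organs, so that each genotype had n = 4 mice in each organ. The comparison of the genotypes asks, organ by organ, which transcripts differ in carriers of the mutation, and the comparison between organs asks whether the effect of the genotype differs from organ to organ.

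Most marker genes checked were found in their organs, but not all were confined to them. The kidney marker Slc34a1 was detected on 8 of 8 kidney arrays, and also on 4 of 8 heart and 2 of 8 brain arrays. Its median signal was 10194.5 in kidney, 116 in heart and 105 in brain. The heart marker Tnni3 was detected on 1 of 8 kidney arrays. Myh6 and Tnni3, which encode cardiac myosin and troponin, were detected on 8 of 8 heart arrays, and Umod, made by the thick ascending limb of the kidney, on 8 of 8 kidney arrays. The probe of Snap25, the brain marker among those checked, was detected on 0 of 8 brain arrays, but the myelin genes Mog and Mobp, looked up after this was seen, were detected on 8 of 8 brain arrays and 0 of 8 arrays of heart and of kidney on each of their probes. The Y-linked gene Eif2s3y was detected on 8 of 8 arrays of each organ. Of all probes on the array, 12626 ± 243 (SD, n = 4) were detected in wild-type brain and 12598 ± 261 in heterozygous brain. In heart the numbers were 12147 ± 349 and 11941 ± 384, and in kidney 10933 ± 280 and 11200 ± 212, and the ranges of the genotypes overlapped in each organ. The number of arrays limits the precision of every value below.

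Arrays also differed along the sample number given in the labels. In brain, the first principal component held 22.1% of the variance and correlated with the sample number with a Pearson r of 0.976 (exact permutation p = 4.96e-05, the smallest these permutations can give) and a Spearman rho of 1 (exact permutation p = 4.96e-05). In heart it held 29.6%, with r of 0.986 (exact permutation p = 9.92e-05) and rho of 0.976 (exact permutation p = 3.97e-04). In kidney it held 31.5%, with r of 0.941 (exact permutation p = 6.45e-04) and rho of 0.881 (exact permutation p = 0.00724). Adjusted over these 3 relations, the p-values of r were 1.49e-04, 1.49e-04 and 6.45e-04 in brain, heart and kidney by exact permutation. Without the 2 mice farthest from the median number, r of the component was 0.992, 0.969 and 0.891. The number of detected probes also went with the sample number, with r of -0.815 in brain and -0.834 in heart (adjusted exact permutation p = 0.0226 and 0.0205), and 0.169 in kidney (adjusted exact permutation p = 0.679); without the same 2 mice r was -0.854, -0.522 and 0.292. The mean sample number was 3.25 in wild-type and 5.75 in heterozygous mice, so genotype and number overlapped in part.

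**Figure D1:**
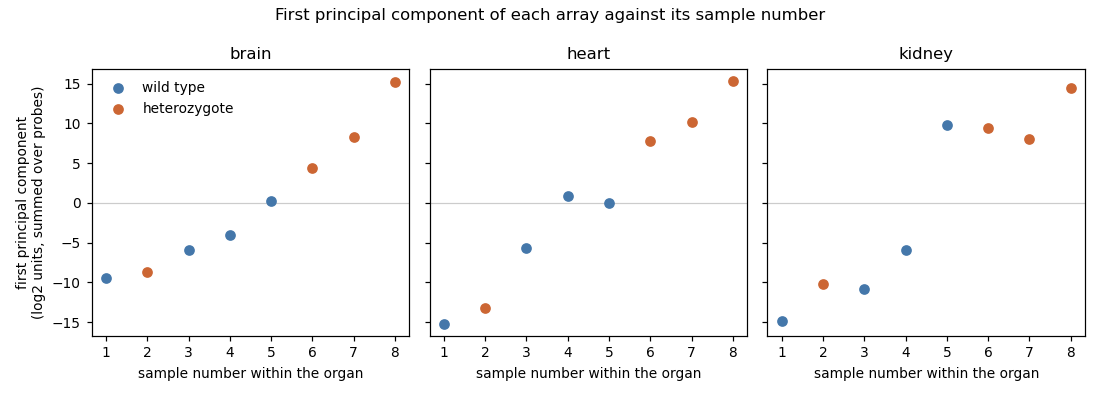
First principal component of each array (log2 units) against its sample number within the organ, for brain, heart and kidney, with 4 wild-type and 4 heterozygous mice per panel. The component follows the number with r of 0.976, 0.986 and 0.941, and the heterozygotes hold the numbers 2, 6, 7 and 8.

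Kidney differed between the genotypes. Pvalb, which encodes the calcium-binding protein parvalbumin of the early distal convoluted tubule, fell in heterozygotes, from a mean log2 intensity of 10.6 ± 0.02 (SD, n = 4) to 9.47 ± 0.08, a log2 change of -1.14 ± 0.09 (SE; limma adjusted p = 5.23e-05). Clu, which encodes the secreted chaperone clusterin, rose by 1.28 ± 0.11 on the log2 scale (adjusted p = 5.23e-05 by limma). The beta-defensin gene Defb2 rose by 1.14 ± 0.11 (adjusted p = 1.53e-04), and a second one, Defb42, by 0.88 ± 0.13 (adjusted p = 0.00848). Wfdc15b, a gene of the whey acidic protein family, fell on both of its probes, with log2 changes of -1.16 ± 0.12 and -0.84 ± 0.11. Sycn, which encodes a protein of secretory granules, changed by -1.30 ± 0.15 (adjusted p = 0.00121), and Rasgrp1, an activator of Ras, by -1.18 ± 0.20 (adjusted p = 0.0183). Defb2 in wild type (mean log2 intensity 4.66), and Sycn (4.66) and Rasgrp1 (4.79) in heterozygotes, were detected on only 3 of 4 arrays. These means lay near the background, where changes shrink, so these sizes are not comparable with those of brighter probes.

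In all, 30 of 10976 kidney probes differed (limma, adjusted p under 0.05), 16 higher and 14 lower in heterozygotes, with log2 changes between 0.56 and 1.30 in size. At an unadjusted p under 0.05 there were 935 probes, against 548.8 if nothing differed. Of single genes, Slc26a4 encodes the chloride-bicarbonate exchanger pendrin and rose by 0.75 ± 0.14, Slc4a9 encodes an anion exchanger and rose by 0.76 ± 0.13, and Bsnd encodes barttin, a subunit of kidney chloride channels, and rose by 0.69 ± 0.12. Scnn1b, the beta subunit of the epithelial sodium channel, rose by 0.67 ± 0.12. The betaine transporter gene Slc6a12 fell, with a log2 change of -0.83 ± 0.11. Sfrp1 and Dkk3, from families of secreted Wnt regulators, moved apart, with changes of -0.85 ± 0.14 and 0.62 ± 0.11. Further genes that fell were Ckb (brain-type creatine kinase) with -0.84 ± 0.12, Bcat1 (branched-chain aminotransferase) with -0.82 ± 0.13, Adssl1 (adenylosuccinate synthase) with -0.72 ± 0.12 and Fabp3 (fatty acid binding protein) with -0.71 ± 0.11, while the phosphoglycerate mutase gene Pgam2 rose by 0.59 ± 0.11. Reep6 rose by 0.96 ± 0.14, Spink8 by 0.95 ± 0.11, Ltc4s (leukotriene C4 synthase) by 0.77 ± 0.12, Abhd4 by 0.73 ± 0.12, Scg5 by 0.73 ± 0.11, the guanylin gene Guca2a by 0.66 ± 0.10 and Rab15 by 0.57 ± 0.11. Olfml2b, near the background in heterozygotes (mean log2 intensity 4.49, detected on 3 of 4 arrays), and Perm1 fell, with changes of -0.84 ± 0.11 and -0.57 ± 0.09. In these named probes the 4 heterozygous values all lay on one side of the 4 wild-type values, as they did in 503 of the 10976 probes (4.58%, against 2.86% by chance).

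The number of kidney probes past the test was 48 without heterozygote replicate 1, 50 without wild-type replicate 4, 19 without wild-type replicate 2 or heterozygote replicate 3, 17 without wild-type replicate 3 or heterozygote replicate 2, and 15 without heterozygote replicate 4. It was 18 with the sample number as a linear term, an alternative chosen after the data were seen, and 15 without background correction, 14 without the detection filter, 4 on the authors' normalized values, 49 with array weights and 134 when all 24 arrays shared 1 fit.

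**Figure D2:**
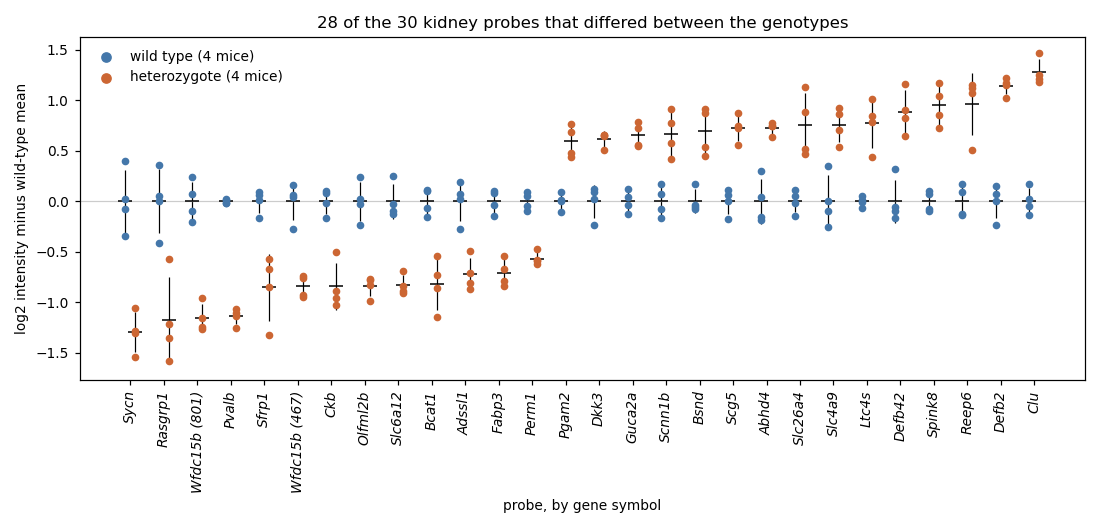
Log2 intensity of 28 kidney probes in each mouse, minus the wild-type mean of the probe; bars give the mean and SD of 4 wild-type and 4 heterozygous mice. Sycn, Rasgrp1, Wfdc15b and Pvalb lie lowest, with log2 changes from -1.30 to -1.14, and Defb2 and Clu highest, at 1.14 and 1.28.

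Genes of intercalated cells, the acid-base transporting cells of the collecting duct system, rose as a group in heterozygous kidney. Of 12 measured genes 11 were higher, with a mean log2 change of 0.34 (camera adjusted p = 1.85e-07, and adjusted p = 0.254 with an estimated correlation). Slc4a9, Slc26a4 and Bsnd rose over all probes tested; adjusted over the list alone, 7 genes were higher and 1 lower. The further ones were Foxi1, the transcription factor of these cells, at 0.59 ± 0.17, the proton pump subunit gene Atp6v1c2 at 0.44 ± 0.13, the ammonia transporter gene Rhcg at 0.38 ± 0.15 and Oxgr1 at 0.30 ± 0.12, while the carbonic anhydrase gene Car2 was lower at -0.41 ± 0.17. The list mean was 6.12 ± 0.08 (SD, n = 4) in wild-type and 6.46 ± 0.09 in heterozygous kidney (exact two-sided permutation p = 0.0286, the smallest that 4 against 4 mice allow). The list was picked by camera on the same arrays, so this permutation test is no independent support. Along the sample number 11 of these 12 genes had positive slopes as well (camera adjusted p = 0.270). With the number in the fit the mean log2 change of the list was 0.27.

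Endothelial genes fell as a group. Of 16 measured genes 14 were lower, with a mean log2 change of -0.26 (camera adjusted p = 1.85e-07, and adjusted p = 0.341 with an estimated correlation). No gene of this list passed over all probes; adjusted over the list alone, 9 were lower and 1, Kdr at 0.29 ± 0.11, higher. Ets1, a transcription factor of vessels, was lower by limma at -0.57 ± 0.12, the fenestration gene Plvap at -0.51 ± 0.14, the receptor gene Tek at -0.45 ± 0.13, Emcn at -0.44 ± 0.14 and Eng at -0.40 ± 0.11. Tie1, Esam, Pecam1 and Egfl7 had values from -0.37 to -0.28. Along the sample number 15 of these 16 genes had negative slopes as well (camera adjusted p = 0.00740, and adjusted p = 0.536 with an estimated correlation), and with the number in the fit the list mean was -0.17. Hba-a1, an alpha-globin gene of red blood cells, was also lower, at -0.44 ± 0.13, when adjusted over its list alone (list adjusted p = 0.0946 by camera). Of 18 genes of fibroblasts and matrix, 4 were lower over the list alone (Pdgfra -0.50, Mmp2 -0.46, Sparc -0.45, Col5a1 -0.37), with an adjusted p of 0.0746 for the list.

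Genes of urine concentration and osmolyte handling fell as a group of 9, of which 7 were lower, with a mean log2 change of -0.22 and a median of -0.13 (camera adjusted p = 0.0177, and adjusted p = 0.280 with an estimated correlation). Slc6a12 passed over all probes; adjusted over the list alone it was joined by the water channel gene Aqp4 at -0.51 ± 0.14. The water channel gene Aqp2 had -0.24 ± 0.10 and the cotransporter gene Slc12a1 -0.47 ± 0.24, the latter at 0.01 once the sample number was in the fit. The call of this list was lost with the sample number in the fit, where its mean was -0.18, without heterozygote replicate 1 and under the stricter detection filter.

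The list of the distal convoluted tubule, the segment that holds Pvalb, did not pass as a group (15 genes, 8 lower, mean log2 change -0.15, median -0.03, camera adjusted p = 0.0641, and adjusted p = 0.534 with an estimated correlation). Besides Pvalb, 4 genes were lower when adjusted over the list alone: the thiazide-sensitive cotransporter gene Slc12a3 at -0.52 ± 0.12, the magnesium channel gene Trpm6 at -0.34 ± 0.11, Egf at -0.53 ± 0.16 and the kinase gene Wnk1 at -0.26 ± 0.10, of which a second probe went the other way at 0.03. Ptges was higher, by at least 1.14-fold, since no wild-type array detected it. The list mean had an exact two-sided permutation p of 0.0286, as did that of intercalated cells, although this list did not pass camera. With the preset correlation the list passed on the authors' values, under the stricter detection filter, with the trended robust prior, with all 24 arrays in 1 fit, with the sample number in the fit (mean -0.19), and without wild-type replicate 1, 2 or 3 or heterozygote replicate 4.

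In the connecting tubule and principal cells, 1 of 13 genes rose (Scnn1b); adjusted over the list alone, the glucocorticoid-inactivating enzyme gene Hsd11b2 was also higher at 0.52 ± 0.15 and Aqp4 lower (list adjusted p = 0.363). In the thick ascending limb, 1 of 11 genes rose (Bsnd), Egf and Ppp1r1a (-0.47 ± 0.13) were lower over the list alone, and Umod had a value of -0.01 ± 0.13 (list adjusted p = 0.372). The early proximal tubule list held no gene past the test among 19 (list adjusted p = 0.372), and in the late part Cyp7b1, a steroid hydroxylase gene, was lower over the list alone at -0.38 ± 0.11 (list adjusted p = 0.237). Of 16 genes of kidney injury, Clu rose and Lcn2, which encodes the siderophore-binding protein lipocalin, was higher over the list alone at 0.52 ± 0.14; Havcr1, the injury marker of the proximal tubule, had -0.40 (list adjusted p = 0.115). Of 5 podocyte genes, Cdkn1c and Ptpro were lower over the list alone, at -0.49 ± 0.13 and -0.33 ± 0.10 (list adjusted p = 0.237). Fabp3 fell and Acaa1b, an enzyme of peroxisomal fatty acid oxidation, was higher over the list alone at 0.35 ± 0.10, among 21 genes (list adjusted p = 0.252). Single genes of other lists were Ier3 at 0.47, Sult1a1 at -0.42, Cyp51 at -0.57 and Mzb1 at -0.31, each past the test over its list alone. Tfap2b, an AP-2 transcription factor of the distal nephron, had values of 0.30 ± 0.13, 0.39 ± 0.13 and 0.47 ± 0.16 on its 3 probes (limma adjusted p = 0.551, 0.401 and 0.400), and the list of the KCTD family and cullin 3 had an adjusted p of 0.361. In all, 3 of 30 kidney lists passed with the preset correlation and 0 with an estimated one.

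**Figure D3:**
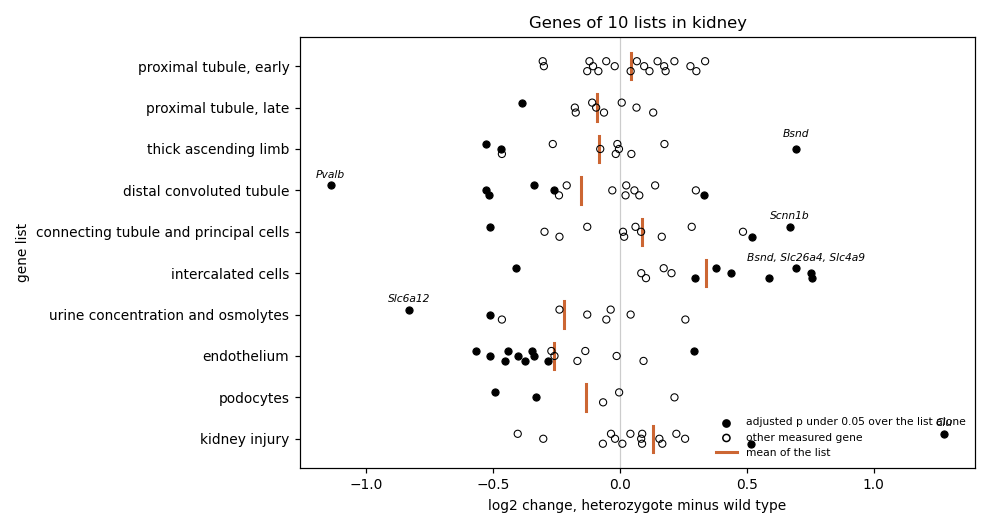
Log2 change (heterozygote minus wild type) of each measured gene of 10 lists in kidney; filled points passed limma over the list alone, and the bar is the mean of the list. The means lie at 0.34 for intercalated cells and at -0.26 for endothelium.

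Brain held no probe past the test. Mbp, which encodes myelin basic protein, came closest, with a log2 change of -0.71 ± 0.12 on 1 probe (n = 4 mice per genotype, limma adjusted p = 0.379), but its other probes had -0.12 and 0.12. The melanoma antigen family gene Tro had 0.58 ± 0.10, Abat, which encodes the enzyme that breaks down GABA, -0.63 ± 0.13, the potassium channel interacting protein gene Kcnip4 -0.59 ± 0.13, the stress kinase gene Eif2ak3 0.47 ± 0.10 and Slc5a7, the choline transporter of cholinergic neurons, -0.39 ± 0.09; none passed, with adjusted p-values from 0.386 to 0.462 by limma. The transcription factor gene Sp5, a target of Wnt signalling, was lower at -0.44 ± 0.09 and Atp2a1, a calcium pump gene of muscle, higher at 0.58 ± 0.15 when adjusted over their lists alone.

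Genes of myelinating oligodendrocytes were lower in heterozygous brain as a group, 11 of 13 genes with a mean log2 change of -0.11 (camera adjusted p = 0.0211, and adjusted p = 0.859 with an estimated correlation). No gene passed, over all probes or over the list alone. Mobp and Mog, both of myelin, had -0.36 ± 0.12 and -0.26 ± 0.09, and Fa2h, which makes hydroxylated myelin lipids, -0.24 ± 0.11. Of the 2 other measured probes of Mobp, 1 went the other way. The list mean was 8.75 ± 0.05 (SD, n = 4) in wild-type and 8.65 ± 0.08 in heterozygous brain (exact two-sided permutation p = 0.0857). Red blood cell genes were lower in 4 of 5 cases (mean -0.17, camera adjusted p = 0.213) and passed without heterozygote replicate 1 and, along with choroid plexus (lower) and olfactory bulb (higher), without wild-type replicate 4. The oligodendrocyte list lost its call with the sample number in the fit, where its mean was -0.09, and without wild-type replicate 1, 2 or 3 or heterozygote replicate 1, 3 or 4. In total 0 of 12608 brain probes passed limma, with 895 at an unadjusted p under 0.05 against 630.4 if nothing differed, and 1 of 32 lists passed. On simulated brain data, the same test found 98 of 100 probes changed by 1 on the log2 scale and 46 of 100 changed by 0.5. Both sets were changed at once, which eases the adjusted threshold, so these shares do not hold for a few changed probes.

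Heart held no probe past the test either. Actg2, which encodes smooth muscle gamma actin, came first, at -0.54 ± 0.10 (n = 4 mice per genotype, limma adjusted p = 0.927). The cytokine receptor gene Il6st had 0.51 ± 0.11, the collagen processing gene Pcolce2 -0.54 ± 0.14, the proteoglycan gene Dcn -0.40 ± 0.10, the collagen-binding integrin gene Itga11 -0.39 ± 0.10 and Ahnak 0.31 ± 0.08, all with an adjusted p of 0.927. The other measured probe of Ahnak went the opposite way. Pparg and Lzts3 were detected on none of the heterozygous arrays and were at least 1.10-fold and 1.11-fold higher in wild type, with other probes that went the opposite way.

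Genes of smooth muscle were lower in heterozygous heart as a group, 7 of 10 with a mean log2 change of -0.15 (camera adjusted p = 0.00892, and adjusted p = 0.399 with an estimated correlation). No gene passed over all probes; adjusted over the list alone, 3 were lower, namely Actg2, Acta2 (smooth muscle alpha actin) at -0.32 ± 0.09 and Myh11 (smooth muscle myosin) at -0.29 ± 0.09. Lmod1 had -0.32 ± 0.14. The list mean was 8.07 ± 0.05 (SD, n = 4) in wild-type and 7.92 ± 0.07 in heterozygous heart (exact two-sided permutation p = 0.0286). Since camera picked this list on the same arrays, the permutation test is no independent support. Genes of macrophages were lower in 14 of 15 cases (mean -0.10, adjusted p = 0.0859 by camera) and those of fibroblasts and matrix in 14 of 24 (mean -0.06, adjusted p = 0.109); neither list passed, though fibroblasts and matrix did without background correction, with the trended robust prior and without wild-type replicate 3 or 4, and macrophages without the detection filter, with the replicate block and without wild-type replicate 3 or 4 or heterozygote replicate 3. Of 12 glucocorticoid targets 9 were higher (mean 0.15, camera adjusted p = 0.0859); this list passed without background correction, with the trended robust prior, array weights, all 24 arrays in 1 fit and the replicate block, and without heterozygote replicate 1 or 3 or wild-type replicate 3 or 4. With the sample number in the fit the adjusted p was 0.982 for macrophages and for fibroblasts and matrix, and 0.847 for glucocorticoid targets. The call of the smooth muscle list was lost without heterozygote replicate 1 and under the stricter detection filter. The sarcomere list (16 genes, adjusted p = 0.663), the cardiac stress list with Nppa at -0.03 and Nppb at -0.07 (13 genes, adjusted p = 0.390) and the atrial list (13 genes, adjusted p = 0.691) did not pass. In total 0 of 12004 heart probes passed limma, with 570 at an unadjusted p under 0.05 against 600.2 if nothing differed, and 1 of 24 lists passed. The test found 97 of 100 simulated heart probes changed by 1 and 59 of 100 changed by 0.5. As in brain, these shares hold for many probes changed at once, not for a few.

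For some genes measured in kidney and another organ, the effect of the genotype differed between them, by within-mouse differences. For Clu the log2 change in kidney exceeded that in brain by 1.31 and that in heart by 1.23. For Pvalb the change in kidney lay below that in brain and heart, with differences of -1.04 and -1.16, and for Olfml2b with -0.95 and -1.17. Slc6a12, Sfrp1 and Rasgrp1 differed between kidney and brain, by -1.11, -0.94 and -1.44, and Reep6 between kidney and heart, by 0.93. Between kidney and brain 12 of 13829 probes differed (limma adjusted p under 0.05, 4 more positive and 8 more negative in kidney), and 11 of them were among the 30 that differed in kidney itself, where the same kidney arrays enter. Between kidney and heart it was 11 of 13190, 6 and 5, and all 11 were among the 30. Of the 12 probes 7 were measured in brain, and of the 11 only 4 in heart. The remaining 5 and 7 (Defb2, Defb42, Sycn and both probes of Wfdc15b in each, with Spink8 and Scg5 for heart) were detected on 0 or 1 of the 8 arrays of the other organ, so that their difference repeats the kidney change. The counts without single mice were 6 to 19 and 4 to 11. Between heart and brain 0 of 14136 probes differed by limma, with 739 at an unadjusted p under 0.05 against 706.8 if nothing differed. Both comparisons with kidney share the kidney arrays.

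**Figure D4:**
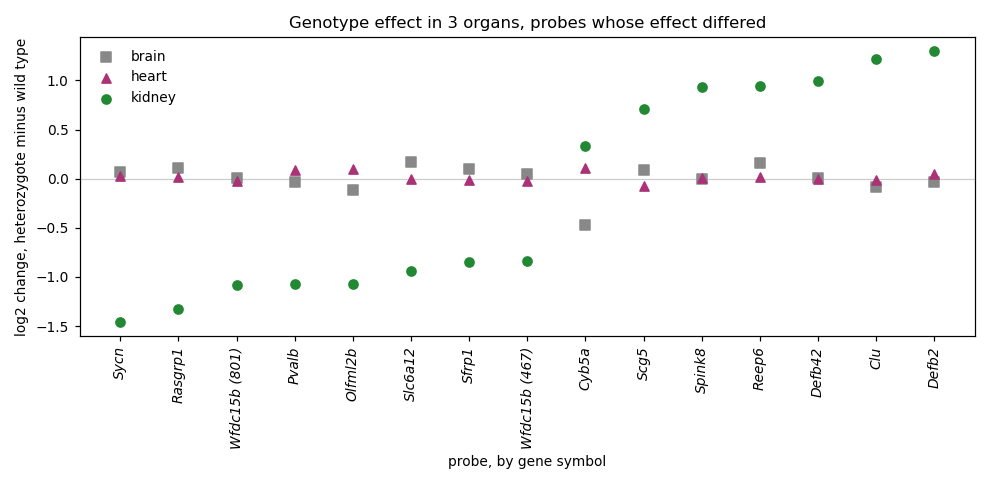
Log2 change (heterozygote minus wild type) in brain, heart and kidney of the probes named by gene whose genotype effect in kidney differed from that in brain or in heart, including probes not detected in the other organ, from values normalized over all 24 arrays (4 mice per genotype). Kidney values run from Sycn to Defb2; Cyb5a has a larger change in brain (-0.47) than in kidney (0.33).

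Averaged over the 3 organs of each mouse, 0 of 9268 probes differed by limma (n = 4 mice per genotype), with 707 at an unadjusted p under 0.05 against 463.4 if nothing differed. Clu had a mean log2 change of 0.37 ± 0.06, Pvalb -0.34 ± 0.06, the ubiquitin ligase gene Huwe1 0.33 ± 0.06, Adssl1 -0.32 ± 0.06, Olfml2b -0.36 ± 0.07 and Mrpl57 -0.28 ± 0.05, each with an adjusted p of 0.246. Of these 6 genes, Clu, Pvalb, Adssl1 and Olfml2b had changed in kidney. The test found 86 of 100 simulated probes changed by 0.5 in all 3 organs. This share too holds for many probes changed at once, not for a few.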

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

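The fit with the sample number as a term, and with it the count of kidney probes that it kept, were chosen only after the results were seen, as were the tests of splits for probes measured in both organs; the other tests in this part were fixed before their results were seen.

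A test of the difference of the genotype effects between kidney and brain called 12 probes, of which 7 were measured in brain. The differences of the log2 changes were 1.34 for Defb2, 1.31 for Clu, 0.98 for Defb42, 0.80 for Cyb5a, -1.04 for Pvalb, -1.53 for Sycn, -1.44 for Rasgrp1, -1.11 for Slc6a12, -0.94 for Sfrp1, -0.95 for Olfml2b, and -1.08 and -0.89 for the 2 probes of Wfdc15b. Cyb5a, the gene of an electron carrier, was the only one of these outside the 30 kidney probes, with effects of -0.47 in brain, 0.11 in heart and 0.33 in kidney. Between kidney and heart it called 11 probes, of which only 4 were measured in heart, with 1.23 for Clu, 1.25 for Defb2, 1.00 for Defb42, 0.93 for Reep6, 0.92 for Spink8, 0.79 for Scg5, -1.17 for Olfml2b, -1.16 for Pvalb, -1.48 for Sycn, and -1.05 and -0.82 for the 2 probes of Wfdc15b. Defb2, Defb42, Sycn and Wfdc15b in both comparisons, and Spink8 and Scg5 against heart, were detected on 0 or 1 of the 8 arrays of the other organ, so these 5 and 7 differences repeat the kidney change and do not test a difference between organs. Of the 35 splits of the 8 mice into 4 and 4, only 1, the real one, gave 12 probes or more for kidney against brain, and the highest other split gave 11. Likewise only 1 gave 11 or more for kidney against heart, with 6 in the highest other, and both counts include probes measured in kidney only. Among probes measured in both organs, the real split gave 7 against brain (highest other 4) and 4 against heart (highest other 1), and only 1 of 35 splits gave as many in each. This is the smallest share that 35 splits can give. The comparisons share the kidney arrays, and these tests were chosen after the results were seen, so chance was not excluded. In each of these comparisons with kidney the highest other split set the sample numbers 1 to 4 against 5 to 8. Between heart and brain the real split gave 0 probes and the highest other 5; with a real count of 0 all 35 of 35 splits are as large by construction, and this says nothing about chance.

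In 17 of 248 groups of 4 mice, or 6.85%, 1 mouse stood apart from the other 3. The measure was a gap, as a share of the range, over the Dixon limit for 4 values, where chance gives about 1 in 20. All 17 were for named genes. The 248 also hold groups for detected probes, median signal and the first principal component, so the share among named genes alone was higher. Kidney of heterozygote replicate 1 stood apart for 5 genes. Reep6 (gap of 0.876) and Trpm6 (0.915) were lower, and Car2 (0.853), Slc12a1 (0.896) and Hba-a1 (0.864) higher. In heterozygous kidney, replicate 2 was lower for Dkk3 (0.887), replicate 3 lower for Oxgr1 (0.900) and replicate 4 lower for Ets1 (0.942). In wild-type kidney, replicate 1 was higher for Bsnd (0.832) and Pecam1 (0.852), and replicate 3 lower for Trpm6 (0.890). In heart, heterozygote replicate 1 was higher for Itga11 (0.931) and Pcolce2 (0.833), and wild-type replicate 4 lower for Itga11 (0.853) and Ahnak (0.911). In brain, wild-type replicate 1 was higher for Cyb5a (0.873) and replicate 4 lower for Gsn (0.893).

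The first pattern is the set of kidney transcripts that differed between the genotypes. For the probes also measured elsewhere, a deviation of whole mice of like size in all organs is argued against. Their brain effects were a median of 0.0321 of their kidney effects (19 of 30 probes, interquartile range -0.0482 to 0.119). Their heart effects were -0.0190 (16 of 30 probes, interquartile range -0.0889 to 0.0352). The probes were chosen on the kidney arrays, which by itself lowers such ratios. Smaller shared deviations are not excluded. Slopes along the sample number correlated between organs over all probes, with r of 0.323 to 0.469. With the number in the fit, the 30 probes kept a median of 0.929 of their change (lowest 0.741), and 17 of 30 passed again. These probes were chosen by genotype on the same arrays, which favours a kept change. The kept share therefore does not decide whether a linear drift along the number is the whole cause. The other 13 went from a median size of 0.69 (median SE 0.12) to 0.60 (median SE 0.12) and lost their call (adjusted p from 0.0920 to 0.240) as changes became smaller and errors larger, by a median factor of 1.15. What the drift adds in part cannot be told apart, because heterozygote replicate 1, with sample number 2 among the wild types, lay at a median position of 0.562 (interquartile range 0.313 to 0.869) between wild type (0) and the other heterozygotes (1) over 48 probes chosen without it, and wild-type replicate 4, with number 5 next to the other heterozygotes, at 0.397 (0.104 to 0.747) over 50, which goes with a drift, while wild-type replicates 1 to 3 lay from 0.0241 to 0.0313 and heterozygotes 2 to 4 from 0.988 to 1.09 with little gradient within either set, and a genotype effect on kidney transcripts stays a hypothesis.

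The same splits bear on that count of kidney probes. Of the 35 splits, 2 gave 30 probes or more, the real one and that of the numbers 1 to 4 against 5 to 8, which gave 401, so chance was not excluded, and the second points to a structure of the samples along the number. With the number in the fit, only 1 split, the real one, gave 18 probes or more, and the highest other gave 2. The split of the numbers 1 to 4 against 5 to 8 gave 0 here, since the number term takes up most of that split. This removes the main rival by construction, and 1 of 35 is the smallest share these splits can give, so chance was not excluded. The average over organs gave 0 probes in the real split and 559 in the same split by number; with a real count of 0 all 35 of 35 splits are as large by construction, which says nothing about chance.

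The second pattern is the distal convoluted tubule in kidney, where Pvalb fell most. Slc12a3, which the whole segment makes, fell less than Pvalb by 0.62 on the log2 scale (SE 0.15, exact permutation p = 0.0286, the smallest 4 against 4 mice allow). Egf fell less by 0.61 (SE 0.19, exact permutation p = 0.0571) and Trpm6 by 0.80 (SE 0.12). Wild-type means were 10.0 for Slc12a3, 10.6 for Pvalb and 5.52 for Trpm6, which lies near the background, where changes shrink, and so excludes nothing. These values argue against fewer cells of the whole segment only if the Slc12a3 and Pvalb probes respond alike. Pvalb was also among the kidney probes of largest change, which favours such a difference. The list mean was -0.19 with the sample number in the fit, against -0.15 without it, so a linear term did not take up this mean. The list did not pass as a group, and 8 of its 15 genes were lower, with a median of -0.03. Its mean therefore does not decide on a drift of the single genes. A loss confined to the part of the segment that makes parvalbumin, lower transcription of Pvalb, and a compressed response of the Slc12a3 probe stay open and were not tested. A candidate explanation is a genotype effect on the early part of this segment.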

How the results depend on the processing

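The fit with the sample number was chosen after the data were seen; all other alternatives were fixed earlier. The 30 kidney probes kept their direction in each alternative and with each mouse left out (24 of 24 that could be measured under the stricter filter). Main counts were 0, 0 and 30 probes and 1, 1 and 3 lists in brain, heart and kidney, 0, 12 and 11 probes for heart against brain, kidney against brain and kidney against heart, and 0 for the average over organs. The causes of the changes below were not tested, except where fewer or more probes or arrays enter by construction.

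With an estimated correlation, 0 lists passed in brain, 0 in heart and 0 in kidney. Without background correction, kidney had 15 probes, heart 4 lists and the average over organs 2 probes. On the authors' values, kidney had 4 probes and 5 lists, kidney against brain 7 probes and kidney against heart 3. Without a detection filter, where more probes are tested, kidney had 14 probes, heart 2 lists, kidney against brain 3 probes and kidney against heart 7. Under the stricter filter heart had 0 lists. With the trended robust prior brain had 1 probe, heart 3 lists and kidney 5 lists. Array weights gave 49 kidney probes and 2 heart lists. With all 24 arrays in 1 fit, brain had 8 probes, heart 2 probes and 2 lists, kidney 134 probes and 6 lists, kidney against brain 47 probes, kidney against heart 53 and the average 4; this fit has more residual degrees of freedom. With the sample number, kidney had 18 probes, heart 2 lists and brain 0 lists, and the log2 change of Slc12a1 in kidney turned to 0.0103 from -0.47. Normalization over all 24 arrays gave 20 kidney probes and an adjusted p under 0.10 gave 44, both within 1.5 times of the main count.

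With 1 mouse left out, the counts ran from 0 to 1 probes in brain (1 without heterozygote replicate 1), 0 to 0 in heart and 15 to 50 in kidney (15 without heterozygote replicate 4, 50 without wild-type replicate 4). They ran from 0 to 4 lists in brain, 1 to 7 in heart and 2 to 6 in kidney, each highest without wild-type replicate 4 except kidney, highest without wild-type replicate 2. They ran from 6 to 19 probes for kidney against brain and 4 to 11 for kidney against heart (4 without heterozygote replicate 4). Over the settings other than a left-out mouse, the 28 named kidney calls gave 274 values, of which 200 still passed and 74 did not, with 0 reversed.

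Mice with the same replicate number were somewhat more alike than others, which was not tested. Their deviations correlated from 0.00983 to 0.0861 in brain, -0.0404 to 0.339 in heart and 0.00893 to 0.289 in kidney. The means were 0.0437, 0.119 and 0.152, against -0.0145, -0.0395 and -0.0522 for mice with different numbers. In brain, heart and kidney 5, 3 and 5 of 8 samples correlated best with their own number. Within each genotype the replicate number rose with the sample number, so this likeness cannot be told apart from a change along the sample number. With the replicate block, brain had 0 probes and 1 list, heart 0 probes and 3 lists, kidney 43 probes and 3 lists, kidney against brain 9 probes, kidney against heart 6, heart against brain 0 and the average 0.

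A slide block was not run because the slides are not given in the sources used here, and a sex term because all arrays showed the same sex. Kctd1 was not analysed here. On the authors' values, 8 named values (Dhx58, Dpysl2, Lzts3, Micall2 and Pparg in heart, Kdr and Ptges in kidney, Gsn in brain) lay at the floor on all arrays and gave no value. Signal over background limits dim genes: 22 of the 28 named kidney calls were measured under the stricter filter, and 22 of these passed.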

Other observations

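The test of the first principal component against the sample number was chosen only after the result was seen, and so was the fit with the number as a term.

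Genes of the circadian clock changed along the sample number, with the genotype in the fit. In heart, 10 of 15 measured clock genes had a positive slope and the list passed (camera adjusted p = 0.00355, and adjusted p = 0.436 with an estimated correlation); adjusted over the list alone, 8 rising and 2 falling genes passed limma. In kidney 10 of 14 had a positive slope (camera adjusted p = 0.00740, and adjusted p = 0.536 with an estimated correlation), and 7 rising and 1 falling passed over the list alone. In brain the list did not pass (adjusted p = 0.451), and 4 rising and 2 falling of 16 genes passed over the list alone. The genes named here were chosen after their values were seen. The clock output gene Dbp had slopes of 0.06, 0.27 and 0.19 per sample number on the log2 scale in brain, heart and kidney, the period gene Per2 had 0.07, 0.29 and 0.17, and Ciart, a repressor in the clock, had 0.10, 0.25 and 0.17. Nfil3, which opposes Dbp on shared promoters, had -0.01, -0.22 and -0.08, and Clock itself -0.06, -0.06 and -0.04.

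Other genes moved along the number as well. With the genotype in the fit, 4 of 12608 probes passed in brain, 146 of 12004 in heart (38 rising, 108 falling) and 140 of 10976 in kidney (28 rising, 112 falling). As a group, endothelial genes went up along the number in heart (positive slopes in 15 of 17, camera adjusted p = 0.00892, and adjusted p = 0.436 with an estimated correlation) and down in kidney (negative slopes in 15 of 16, camera adjusted p = 0.00740, and adjusted p = 0.536 with an estimated correlation). In heart, genes of fibroblasts and matrix and of macrophages went down (adjusted p = 0.00892 for each list, and adjusted p = 0.436 and 0.482 with an estimated correlation). In brain, red blood cell genes went down (adjusted p = 0.0265, and adjusted p = 0.798 with an estimated correlation). The number of detected probes fell along the number in brain and heart too (r of -0.815 and -0.834), and array or RNA quality as a cause of these changes was not tested.

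The third pattern is the leading axis of variation between arrays. A drift along the sample number goes with it in all 3 organs, with a largest exact permutation p of 0.000645 for the Pearson correlation and 0.00724 for the rank correlation, both in kidney. Mice taken in the order of the number at different times of day are a candidate explanation of that drift. Over 13 clock genes the slopes correlated between organs, across genes that are not independent, with r of 0.642 for brain and heart, 0.599 for brain and kidney and 0.911 for heart and kidney, a median of 0.642 against 0.355, 0.323 and 0.469 over all probes. This median fell short of the value set beforehand, so time of day cannot be told apart from other changes along the number, such as the order of dissection or of array processing, and a genotype effect on this axis was not tested.

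For the counts of brain and heart probes, the real split gave 0 in brain and 0 in heart and the highest other 0 in both; all 35 of 35 splits of the 8 mice are as large by construction, which says nothing about chance. For the gene lists, 15 of 35 splits gave as many as the real 1 in brain (highest other 3), 30 of 35 as many as the real 1 in heart (highest other 7) and 17 of 35 as many as the real 3 in kidney (highest other 6). Chance was not excluded for these list counts.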
